A study of Homo sapiens with 38 samples.

How the data were processed

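RNA from laser-captured cancer cells and adjacent stromal cells of 19 patients with pancreatic ductal adenocarcinoma was measured by RNA sequencing. Per the labels' protocols, captured tissue was collected on macro caps, RNA was isolated with a kit for very small samples, cDNA was amplified with the SMARTer kit for ultra-low input, and libraries were made with Nextera XT. Per the submitters' processing notes, STAR 2.4.0h, Picard and HTSeq were used with the human build hg38 (GRCh38). The labels do not say by which marker or morphology cells were chosen. The annotation release, the strand setting and the handling of PCR duplicates are not given in the sources used here. The authors deposited raw counts per gene symbol, as whole numbers with no normalization, in 1 table per compartment with 19 libraries each, and no column lacked a sample (0 unmatched). This library kit does not mark strand, so reads of a gene and of an overlapping antisense gene cannot be told apart, and near-identical genes can share or lose reads. Reads carry no molecular identifiers, so amplification of little RNA adds to the spread between libraries.

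The tables held 59166 rows. The 92 rows of ERCC spike-ins, synthetic RNAs added to samples, were left out of library sizes and tests and are given as a share of counts. Y-linked genes and the transcripts of X inactivation (433 rows) were left out of all tests. Spreadsheet conversion had turned 28 gene names into dates, and these rows were tested but not named. Gene totals, ERCC included, ranged from 1267986 to 6438460 in cancer and from 851421 to 4440654 in stroma. At this depth, a gene at a few CPM rests on a handful of reads per library. Positions are those of GENCODE 29 (GRCh38) by symbol, which gave a position for 93.5% of tested genes. Lists used 3 older symbols as the tables hold them.

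Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, total count 15), libraries were scaled by TMM factors, and glmQLFit and glmQLFTest were run with robust estimation and terms for patient and compartment. P-values were adjusted by the Benjamini-Hochberg method over 12373 genes, with a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic. The common biological coefficient of variation was 0.931. Levels in CPM are means over 19 libraries with TMM factors. Log2 fold changes are those of the fit with patient terms, so they can differ from the log2 ratio of these means. Gene lists, 38 in all with 492 genes, were fixed before the data were examined, from general knowledge of pancreatic cancer and its cell types, not from these samples. The 34 lists with at least 3 tested members were tested with camera (limma 3.58.1) on voom values with the patient block and a preset correlation of 0.01. They were tested again with an estimated correlation, and with fry. With the preset, 18 lists were higher in stroma and 7 in cancer, with the estimate 7 and 2, and with fry 18 and 8. Fry asks whether a list's genes move in one direction on balance and compares them with no other genes.

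Scores were means of log2 CPM (prior count 2) over a list's tested members. Relations between scores were tested with 100000 permutations, two-sided, and adjusted within a family of 48 relations between compartments and within one of 6 inside a compartment. The smallest p these permutations can give is 1e-05. Within-pair differences were tested by flipping signs at random 100000 times. Pairs come from the patient label shared by the 2 libraries of a tumour. Over the 2000 most variable genes, deviations from the compartment means correlated at a mean of 0.344 between libraries of the same patient and −0.018 between libraries of different patients, and the correlation was over 0.1 in 18 of 19 pairs. Within each compartment, no 2 libraries held identical counts. The labels give no sequencing batch, so no value within batches could be computed.

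Named genes follow a rule fixed before the data were examined. It takes the 12 largest fold changes in each direction among genes with an adjusted p under 0.05, an average log2 CPM of at least 4 and the same sign in 17 of 19 pairs. It also takes up to 4 genes with the smallest p in each list and up to 3 passing genes that go against the list's median, and, for relations, those past the threshold or the 3 with the smallest p. Sex-linked genes, immunoglobulin and T cell receptor segments in the first part, and genes without a symbol were skipped. The rule named 161 genes. Some of them are not reported here.

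The scripts were tested on simulated counts for the 12373 genes of stroma against cancer, with 200 changed genes (average log2 CPM above 3) and the real dispersions and library sizes. EdgeR's quasi-likelihood test recovered 4% of genes changed by 2-fold, 40% by 4-fold, 68% by 8-fold and 94% by 16-fold, with 1 false call among 104. The simulated counts were drawn from edgeR's own fitted means and dispersions, so these shares need not hold for the real counts. Alternatives were no patient block, DESeq2 1.42.0, limma-voom with quality weights, with the patient as a random effect or without weights, other scaling factors, other filters, thinning to equal totals, pairs of low total left out, an acinar covariate, a test against 1.5-fold and each pair left out. For scores they were other prior counts, z-scores, partial correlations and patients left out. Scores and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.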

Results

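RNA was sequenced from pancreatic ductal adenocarcinoma, the common gland-forming cancer of the pancreas, in tissue of 19 patients. Cancer cells and stromal cells lying within 280 μm of them were cut out separately by laser capture microdissection, in which a laser lifts chosen cells from a tissue section. Each patient gave 1 cancer library and 1 stroma library, so the 38 libraries form 19 pairs, and the compartments were compared within patients. Counts assigned to genes had a median of 2785301 per cancer library (range 1167843 to 6352804) and of 2386512 per stroma library (range 748997 to 4431094). The difference between compartments did not pass a two-sided sign-flip permutation test (p = 0.057, stroma higher in 8 of 19 pairs). A median of 16560 genes had reads in cancer libraries and of 14448 in stroma libraries (p = 0.0067, stroma higher in 7 of 19 pairs). Synthetic spike-in RNA took a median of 1.36% of counts in cancer and 2.95% in stroma (p = 0.11), and mitochondrially encoded genes took 6.69% and 7.94% of counts (p = 0.62). By the summed level of matrix genes within pairs, 1 library did not match its group's labels. In its pair, matrix genes summed to 349 CPM in stroma and 1533 CPM in cancer. Epithelial genes were lower in the stroma library of this pair, at 0.777 times the cancer level, the highest such ratio of the 19 pairs. Their sum of 9366 CPM in this library was the highest among stroma libraries, and the median of cancer libraries was 9359 CPM. The library was kept in the main test.

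The first comparison asked which genes differ between cancer cells and the stroma beside them. Lists of epithelial and basal-like tumour genes were higher in the cancer captures, and lists of fibrous matrix, activated and myofibroblastic stroma and macrophages in the stroma captures, by camera with a preset and with an estimated correlation. Mucins, endoderm transcription factors and the classical subtype in cancer, and antigen presentation genes in stroma, passed with the preset alone (adjusted p = 0.0537, 0.0723, 0.0715 and 0.0715 with an estimated correlation). Of 12373 genes tested, 638 were higher in stroma and 865 higher in cancer at an adjusted p under 0.05 in edgeR's quasi-likelihood test with the patient as a block. Of these, 569 and 775 differed by at least 2-fold, and 10870 genes did not pass. Without the block for the patient pairing, the counts were 524 and 222. They were 338 and 482 when the 4 pairs holding a library with under 50% of the median total were left out, and 756 and 896 without the pair of the library that did not match its labels.

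Among genes with an average log2 CPM of at least 4 and the same sign in 17 of 19 pairs, the largest difference in stroma was that of ADAM33, a membrane-bound metalloprotease (chromosome 20, 3667965 to 3682246, GRCh38). Its mean level was 4.44 ± 7.02 CPM (counts scaled to a common library total) in cancer and 56.2 ± 49.1 CPM in stroma (SD, n = 19). The log2 fold change fitted within patients, which is not the ratio of these means, was 5.30 ± 0.84 (SE). Its adjusted p was 0.000127 from edgeR's quasi-likelihood test, and stroma was higher in 18 of 19 pairs. ADAM33 had reads in 9 of 19 cancer libraries and in 18 of 19 stroma libraries. COMP, a cartilage matrix protein (chromosome 19, 18782773 to 18791314), was at 48.4 ± 47.5 CPM in cancer and 614 ± 685 CPM in stroma (SD, n = 19), and SFRP4, a secreted Wnt antagonist (chromosome 7, 37905932 to 38025695), at 69.4 ± 110 and 458 ± 429 CPM. SFRP4 was higher in stroma in 19 of 19 pairs. The elastic fibre gene ELN rose by a log2 fold change of 3.86 in stroma, HGF, the ligand of the receptor MET, by 3.87, and CHRD, an antagonist of bone morphogenetic proteins, by 4.09. CD200, a ligand that restrains myeloid cells, had a log2 fold change of 3.89. AMICA1 (4.62), FGF14 (4.09), TMEM200A (4.08), ZNF521 (3.96) and ABCA6 (3.63) completed the 12 genes, all with 17 or more pairs in the same direction.

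Among genes that met the same limits on level and pairs, the largest differences in the cancer captures were those of SMIM6 (log2 fold change of stroma over cancer −4.94 ± 0.83, SE), BSPRY (−4.47 ± 0.74) and CKMT1B (−4.42 ± 0.78). BSPRY (chromosome 9, 113349541 to 113371233) was at 37.0 ± 22.8 CPM in cancer and 3.04 ± 4.08 CPM in stroma (SD, n = 19) and was higher in cancer in 19 of 19 pairs, with an adjusted p of 0.000196 from edgeR's quasi-likelihood test. CKMT1B, a mitochondrial creatine kinase, has a near-identical copy in the genome, so its counts are uncertain. KRT80, a keratin (chromosome 12, 52168996 to 52192000), was at 76.8 ± 106 CPM in cancer and 9.12 ± 14.3 CPM in stroma (SD, n = 19). FOXA3, a transcription factor of endoderm (chromosome 19, 45863989 to 45873797), was at 45.6 ± 37.8 and 11.2 ± 26.4 CPM. The others were the nucleoside transporter SLC29A2 (−4.28), the secreted protease KLK11 (−4.24), the sphingolipid phosphatase SGPP2 (−4.16), PLEK2 (−3.95), ARL14 (−3.88), the reductase AKR7A3 (−3.76) and the steroid dehydrogenase HSD17B2 (−3.73).

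**Figure D1:**
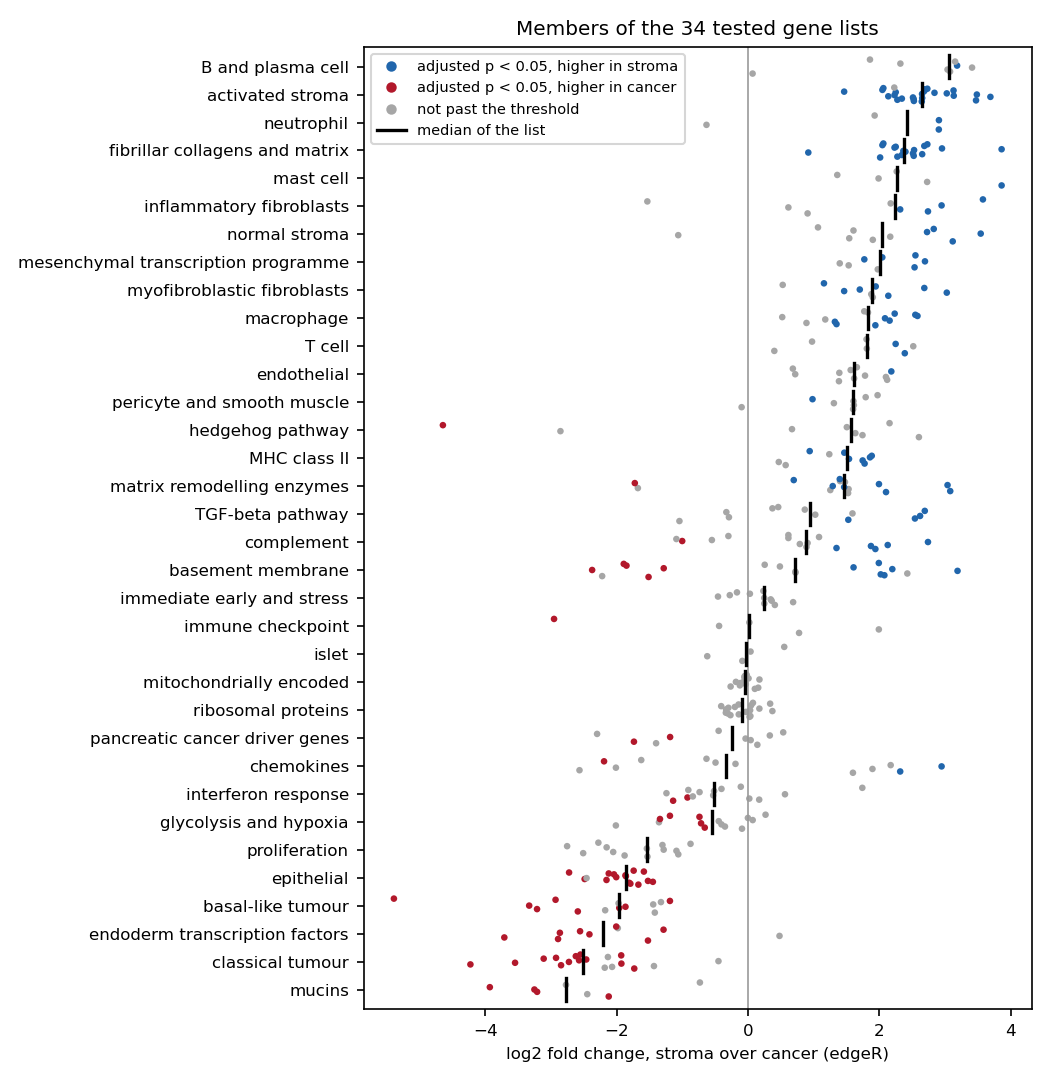
Log2 fold change of stroma over cancer (x axis) for each measured member of the 34 tested gene lists (rows, ordered by median). Points are genes, coloured where they passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and black bars are list medians. The 18 matrix genes all lie on the stroma side, while basement membrane genes lie on both sides.

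Epithelial identity was the most uniform feature of the cancer captures. Of 16 epithelial genes measured, 15 were higher in cancer over all genes tested and 16 adjusted over the list alone, with a median log2 fold change of −1.86. KRT19, a keratin of duct cells (chromosome 17, 41523617 to 41528308), was at 1494 ± 901 CPM in cancer and 433 ± 323 CPM in stroma (SD, n = 19), and was higher in cancer in 19 of 19 pairs (edgeR quasi-likelihood, adjusted p = 3.18e-06). KRT8 (log2 fold change −2.04), the tight junction gene CLDN4 (−1.79) and the membrane protease gene ST14 (−1.58) were lower in stroma as well. The list was lower in stroma by camera, a test of a list against all other genes (adjusted p = 3.03e-14), and with an estimated correlation (adjusted p = 0.0434).

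Genes of both published tumour subtypes were higher in cancer cells. Of 18 measured genes of the classical subtype, 13 were higher in cancer (16 adjusted over the list alone, median −2.51), among them FAM3D (−3.55), LGALS4 (−2.73), VSIG2 (−2.55) and ST6GALNAC1 (−3.11). Camera gave an adjusted p of 9.31e-10 for this list, and the adjusted p was 0.0715 with an estimated correlation. Of 13 basal-like genes, 8 were higher in cancer (11 adjusted over the list alone, median −1.97), including the long noncoding RNA UCA1 (−5.39), CST6 (−2.59), KRT7 (−1.86) and TNS4 (−2.93). This list passed camera with the preset (adjusted p = 5.74e-07) and with the estimated correlation (adjusted p = 0.0434).

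Transcription factors of endoderm, the embryonic layer that forms gut and pancreas, were higher in cancer for 8 of 10 measured members (8 adjusted over the list alone, median −2.21). FOXA2 (−2.89), FOXA3 (−3.71), KLF5 (−1.28) and SOX9 (−2.00) were among them. Camera gave an adjusted p of 3.32e-05, and 0.0723 with an estimated correlation. Mucin genes, which encode the glycoproteins of mucus and of the apical surface, were higher in cancer for 4 of 7 (6 adjusted over the list alone, median −2.77). MUC4 (−3.25), MUC5AC (−3.93), MUC20 (−3.21) and MUC1 (−2.12) passed. The camera adjusted p was 5.15e-06, and 0.0537 with an estimated correlation.

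Of 10 genes often altered in pancreatic cancer, 2 were higher in cancer and 8 did not pass (3 adjusted over the list alone, median −0.24; camera adjusted p = 0.248). The list passed fry (adjusted p = 0.0184), and its summed level differed by a mean of −0.32 in log2(sum + 1), with stroma higher in 5 of 19 pairs (sign-flip permutation test over 38 lists, adjusted p = 0.015). The receptor gene ERBB2 had a log2 fold change of −1.74, RNF43 −2.30 and CDKN2A −1.40, of which the last 2 did not pass over all genes. No proliferation gene of 13 passed over all genes in edgeR's quasi-likelihood test, and 5 passed adjusted over the list alone, all with a negative fold change. At an unadjusted p under 0.05, 7 of the 13 passed, and DESeq2 called 8, limma-voom with quality weights 9, with the patient as a random effect 1 and without weights 5. CCNB1 (−2.51) and UBE2C (−2.28) had the values of adjusted p 0.0668 and 0.0647 from edgeR's quasi-likelihood test. The proliferation list had a median of −1.54 and a camera adjusted p of 0.00204, and an adjusted p of 0.132 with an estimated correlation. Without the patient block its median was −0.77 and its adjusted p 0.0526. In the list of glycolysis and hypoxia, 5 of 14 genes were higher in cancer (8 adjusted over the list alone, median −0.55), including PFKP (−1.34), PKM (−0.74), GAPDH (−0.71) and ALDOA (−0.66), the last of which lost its call in 1 of 19 cases with 1 pair left out. Its camera adjusted p was 0.00204, and 0.0715 with an estimated correlation, and without the patient block it was 0.299.

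The stroma captures were rich in matrix genes. All 18 genes of the fibrillar collagen and matrix list were higher in stroma (18 adjusted over the list alone, median 2.38). COL6A3, a chain of microfibrillar collagen (chromosome 2, 237324003 to 237414375), was at 263 ± 245 CPM in cancer and 1195 ± 809 CPM in stroma (SD, n = 19), with an adjusted p of 2.49e-05 from edgeR's quasi-likelihood test. COL5A2 (log2 fold change 2.51), POSTN (2.69) and THBS2 (2.73), genes of matrix proteins, were higher in 18 of 19 pairs each. Camera gave an adjusted p of 1.82e-37, and 0.00783 with an estimated correlation. Of 25 genes of the activated stroma list, which shares 11 genes with the matrix list, 24 were higher in stroma (25 adjusted over the list alone, median 2.65), among them FNDC1 (3.49) and the fibroblast cadherin CDH11 (2.65). Its camera adjusted p was 6.04e-46, and 0.00783 with an estimated correlation.

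The matrix remodelling list had 8 genes higher in stroma, 1 higher in cancer and 6 that did not pass (12 and 2 adjusted over the list alone, median 1.47). LOX, which crosslinks collagen, was at 22.9 ± 27.2 CPM in cancer and 149 ± 139 CPM in stroma (SD, n = 19). MMP19 (3.04), TIMP2 (1.4) and TIMP1 (0.70) were also higher in stroma. MMP7, a matrix protease of glandular epithelium, went the other way, with 1075 ± 1042 CPM in cancer and 470.0 ± 694 CPM in stroma (log2 fold change −1.72 ± 0.42, SE). The list passed camera (adjusted p = 9.26e-09) and the estimated correlation (adjusted p = 0.0267). Basement membrane genes divided: of 17 measured, 6 were higher in stroma and 5 in cancer (8 and 6 adjusted over the list alone, median 0.72). The collagen and laminin genes COL4A2 (2.02), LAMA2 (3.19), LAMA4 (2.20) and LAMB1 (1.61) were higher in stroma, and the laminin genes LAMA3 (−2.37), LAMB3 (−1.85) and LAMA5 (−1.28) in cancer. The list's camera adjusted p was 0.0158, and the adjusted p was 0.095 with an estimated correlation and 0.381 without a filter on low counts.

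Of 10 myofibroblastic genes, 7 passed (10 adjusted over the list alone, median 1.89), including MYL9 (1.70), TPM2 (1.16) and INHBA (3.03), with a camera adjusted p of 2.43e-12, and 0.0267 with an estimated correlation. Of 13 inflammatory fibroblast genes, 8 were measured and 4 were higher in stroma (5 higher and 1 lower adjusted over the list alone, median 2.25): the chemokine genes CXCL12 (2.95) and CCL2 (2.32), the complement gene C7 (2.74) and the growth factor receptor PDGFRA (3.58). The 1 lower in stroma was the cytokine gene LIF (−1.53), and the cytokine gene IL6 was not measured. The camera adjusted p of the inflammatory list was 0.000617, and 0.0715 with an estimated correlation. The normal stroma list had 4 of 10 genes higher in stroma (7 adjusted over the list alone, median 2.04), ID4 (3.55), ABCA8 (3.12), OGN (2.83) and LMOD1 (2.73). With 1 pair left out, CCL2, OGN and LMOD1 lost their call in 13 of 19 cases each and ABCA8 in 8. Mean levels of CCL2 were close, at 90.0 ± 215 CPM in cancer and 102 ± 110 CPM in stroma (SD, n = 19), and stroma was higher in 14 of 19 pairs. The normal stroma list had a camera adjusted p of 8.1e-05, and 0.0747 with an estimated correlation. Of 8 mesenchymal genes, 5 were higher (5 adjusted over the list alone, median 2.01), among them the transcription factors ZEB1 (2.05), ZEB2 (2.55) and PRRX1 (2.54) and the filament gene VIM (1.77), with a camera adjusted p of 2.09e-07, and 0.0434 with an estimated correlation.

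Of 12 genes of the transforming growth factor beta (TGF-beta) pathway, 4 were higher in stroma (6 adjusted over the list alone, median 0.95), among them the ligand TGFB3 (2.69) and its binding proteins LTBP1 (1.53) and LTBP2 (2.54). The camera adjusted p was 6.52e-05, and 0.0715 with an estimated correlation. In the hedgehog list, 1 of 8 genes passed. The ligand SHH (chromosome 7, 155799986 to 155812273) was at 24.8 ± 23.1 CPM in cancer and 1.90 ± 3.3 CPM in stroma (SD, n = 19). Its log2 fold change fitted within patients was −4.64 ± 0.84 (SE), with an adjusted p of 0.000518 from edgeR's quasi-likelihood test. IHH had −2.85, SMO 2.16 and GLI1, a transcription factor induced by the pathway, 2.60 ± 1.03 (SE), none of which passed edgeR's quasi-likelihood test. Of the 8 hedgehog genes, DESeq2 called 6, limma-voom with quality weights 8, without weights 5 and with the patient as a random effect 5. GLI1 was higher in stroma in 15 of 19 pairs. The list's median was 1.57 and its camera adjusted p 0.165. Its summed level differed by a mean of 0.72 in log2(sum + 1), with stroma higher in 16 of 19 pairs (sign-flip permutation test over 38 lists, adjusted p = 0.032).

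Immune cell genes were higher in stroma, in part. Of 13 macrophage genes, 8 passed (9 adjusted over the list alone, median 1.83), with MSR1, a scavenger receptor, at 40.7 ± 43.2 CPM in cancer and 144 ± 126 CPM in stroma (SD, n = 19) and higher in 19 of 19 pairs. MRC1 (2.58), C1QA (1.94) and MS4A4A (2.55) also passed, and camera gave an adjusted p of 2.07e-10, and 0.0477 with an estimated correlation. Of 10 genes of major histocompatibility complex (MHC) class II, which present antigen to T cells, 7 were higher (9 adjusted over the list alone, median 1.5), including HLA-DRA (1.47), HLA-DPA1 (1.54), HLA-DQA1 (1.89) and HLA-DMB (1.75), with an adjusted p of 2.02e-07 by camera, and 0.0715 with an estimated correlation. These genes have close paralogs that can share reads. Of 7 T cell genes, CD2 (2.39) and IL7R (2.25) passed (3 adjusted over the list alone, median 1.81, camera adjusted p = 0.000475), and the adjusted p was 0.0715 with an estimated correlation. Of 8 B and plasma cell genes, IGKC (3.19) passed, and 5 passed adjusted over the list alone (median 3.06). The camera adjusted p was 2.76e-08, and 0.0434 with an estimated correlation. CSF3R (2.91) and FPR1 (2.91) passed among 4 neutrophil genes (3 adjusted over the list alone, median 2.42), and CPA3 (3.86) among 5 mast cell genes (4 adjusted over the list alone, median 2.27). With 1 pair left out, IGKC lost its call in 15 of 19 cases, IL7R in 14, HLA-DRA in 6, CD2 in 5 and HLA-DQA1 in 2. The neutrophil and mast cell lists had a camera adjusted p of 0.0008, with an estimated correlation 0.0715 and 0.0957 as adjusted p. The summed neutrophil level did not pass the sign-flip permutation test (mean 0.82 in log2(sum + 1), stroma higher in 15 of 19 pairs, adjusted p = 0.22).

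PECAM1, an endothelial adhesion gene (log2 fold change 2.18), was the 1 of 11 endothelial genes that passed (2 adjusted over the list alone, median 1.62), and NOTCH3 (0.98) the 1 of 8 pericyte and smooth muscle genes (5 adjusted over the list alone, median 1.61). Both lists had a camera adjusted p of 8.1e-05, and adjusted p of 0.124 and 0.0783 with an estimated correlation. Of 15 complement genes, 5 were higher in stroma and 1 in cancer (6 and 3 adjusted over the list alone, median 0.89): C1R (1.87), C1S (2.13), C1QA and C7 among the former, and CD55, an inhibitor of complement on cell surfaces, the latter (−1.0). With 1 pair left out, NOTCH3 lost its call in 13 of 19 cases and CD55 in 12. The camera adjusted p was 0.000233, and 0.0747 with an estimated correlation.

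Other lists did not pass camera. Of 12 chemokine genes, CXCL12 and CCL2 were higher in stroma and CXCL3, an attractant of neutrophils, in cancer (−2.19); 4 and 3 passed adjusted over the list alone (median −0.34, mean 0.10, camera adjusted p = 0.412). Of 14 interferon response genes, IFI27 (−1.14) and IFI6 (−0.92) were higher in cancer (2 adjusted over the list alone, median −0.52, camera adjusted p = 0.34). The summed level of the interferon list differed by a mean of −0.64 in log2(sum + 1), with stroma higher in 4 of 19 pairs (sign-flip permutation test over 38 lists, adjusted p = 0.0013). VTCN1 (−2.95), an inhibitory ligand of T cells, was the 1 of 5 immune checkpoint genes that passed (1 in each direction adjusted over the list alone, median 0.02, mean −0.12, camera adjusted p = 0.535). With 1 pair left out, VTCN1 lost its call in 9 of 19 cases, CCL2 in 13 and IFI6 in 1. No gene passed in edgeR's quasi-likelihood test among 4 islet, 11 immediate early and stress, 13 mitochondrially encoded and 18 ribosomal protein genes, over all genes or adjusted over the list alone, with camera adjusted p of 0.218, 0.145, 0.958 and 0.096. At an unadjusted p under 0.05, 0 islet, 1 immediate early, 0 mitochondrial and 2 ribosomal genes passed. DESeq2 called 0, 1, 0 and 1 of them, limma-voom with quality weights 0, 3, 1 and 4, without weights 0, 1, 0 and 4, and with the patient as a random effect 0 in each list. The ribosomal list (median −0.08) passed camera as higher in cancer without a filter, with the filter planned as stricter, and without the pairs of low total (adjusted p = 9.65e-06, 0.0336 and 0.0192).

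Lists with fewer than 3 genes past the count filter were compared as summed CPM of all their members, by the mean within-pair difference of log2(sum + 1) over the 38 lists. Acinar genes, most of which encode digestive enzymes, differed by −2.41 ± 2.67 (SD, n = 19 pairs), with stroma higher in 4 of 19 pairs (two-sided sign-flip permutation p = 0.00047, adjusted p = 0.0014). Their median was 594 CPM in cancer and 195 CPM in stroma. REG1A made up much of these sums, with means of 986 CPM in cancer and 882 CPM in stroma, against 1918 and 964 CPM for the list. PRSS3 had medians of 67.5 CPM in cancer and 23.5 CPM in stroma. The enzyme genes CPA1, CTRB1, CELA3A and PNLIP had medians of 0 CPM in both compartments. The acinar gene PRSS3, which has close paralogs, passed over all genes in edgeR's quasi-likelihood test (log2 fold change −2.57, adjusted p = 0.0101), and REG1A did not (−2.32). The red blood cell gene HBB had a log2 fold change of −0.03 and the nerve and stroma gene GPM6B −1.06 (edgeR quasi-likelihood, adjusted p = 0.985 and 0.515). Schwann and nerve genes (−0.15, adjusted p = 0.83), adipocyte genes (0.05, adjusted p = 0.95) and red blood cell genes (0.29, adjusted p = 0.73) did not pass the same permutation test, nor did islet genes (−0.79, adjusted p = 0.38).

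**Figure D2:**
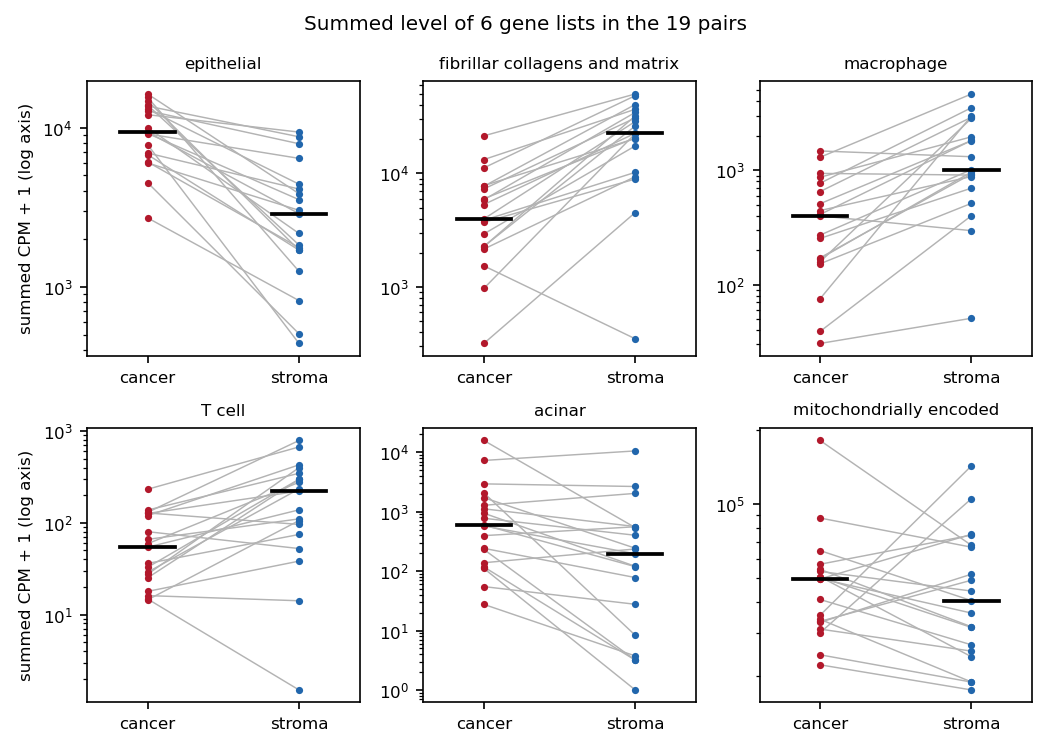
Summed CPM plus 1 (log axis) of 6 gene lists in cancer and stroma libraries. Each line joins the 2 libraries of a patient, and black bars are medians over 19 libraries. Epithelial genes are lower in stroma in all 19 pairs, and matrix genes higher in 18 of 19.

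A further comparison asked how cleanly the compartments were separated. The summed level of 16 epithelial genes in a stroma library was a median of 0.302 times that in the cancer library of the same patient (range 0.0562 to 0.777, below 1 in 19 of 19 pairs). The summed level of 18 matrix genes in a cancer library was a median of 0.231 times that in the paired stroma library (range 0.0432 to 4.40, below 1 in 18 of 19 pairs). Fold changes between the compartments are therefore measured between captures that each hold transcripts typical of the other.

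Scores, the mean log2 CPM over a list's members, were then related to each other across the 19 patients within one compartment, for 6 relations fixed beforehand. In cancer libraries the classical subtype score rose with the score of endoderm transcription factors, with which it shares no gene. Pearson's r was 0.83 (permutation p = 6e-05, adjusted p = 0.00036), Spearman's rho 0.76 (permutation p = 0.00031), and r was 0.81 without the 2 patients farthest from the median of the classical score. Among the 16 libraries above the widest gap in the endoderm score, r was 0.847 (permutation p = 0.00015), and the 3 below it were too few for a value. The classical score did not follow the basal-like score (r = −0.06, permutation p = 0.8, adjusted p = 0.8, 95% interval −0.50 to 0.40; rho = −0.02, permutation p = 0.93; r = 0.04 without the 2 farthest patients). The basal-like score did not follow glycolysis and hypoxia, with which it shares 1 gene (r = 0.07, permutation p = 0.79, adjusted p = 0.8; rho = 0.06, permutation p = 0.8; r = 0.16 without the 2 farthest patients).

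In stroma libraries the T cell and macrophage scores rose together (r = 0.69, permutation p = 0.00088, adjusted p = 0.0026; rho = 0.66, permutation p = 0.0025), with r of 0.66 without the 2 farthest patients and 0.571 (permutation p = 0.0172) among the 17 libraries above the widest gap in the macrophage score. Myofibroblastic and inflammatory fibroblast scores had r = 0.69 (permutation p = 0.0092, adjusted p = 0.018) and rho = 0.20 (permutation p = 0.41). Activated and normal stroma scores had r = 0.65 (permutation p = 0.013, adjusted p = 0.019) and rho = 0.26 (permutation p = 0.29). Without the 2 farthest patients, r was 0.46 and −0.001 for these pairs of scores, and without the pair of the library that did not match its labels 0.24 and 0.20 (permutation p = 0.33 and 0.42). Both relations rest on those samples.

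**Figure D3:**
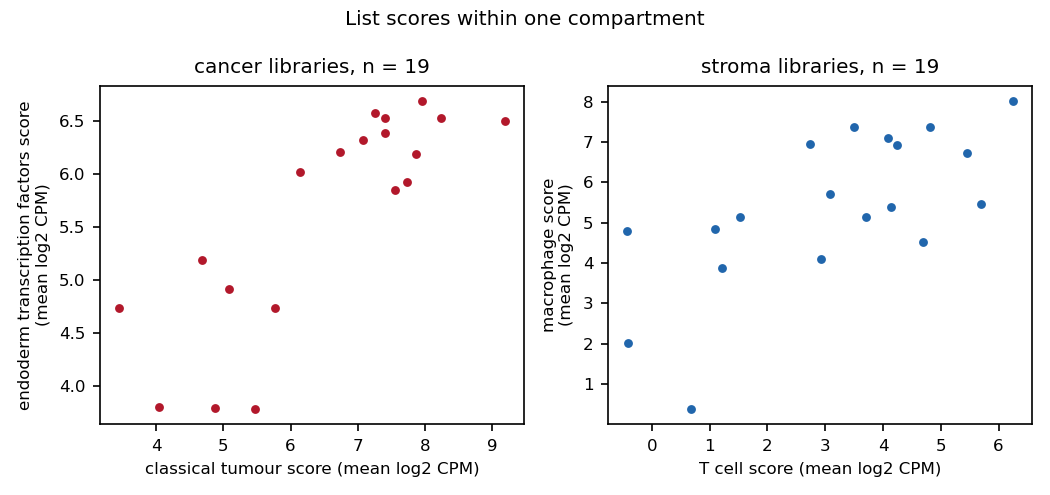
List scores (mean log2 CPM) of 19 patients, each point being 1 library. Left, endoderm transcription factors (y) against the classical subtype (x) in cancer libraries, r = 0.83. Right, macrophage (y) against T cell (x) in stroma libraries, r = 0.69.

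The last comparison asked whether the state of the cancer cells goes with the state of the adjacent stroma. None of 48 relations between a cancer score and a stroma score passed after adjustment by Pearson's r or Spearman's rho, and 6 had an unadjusted permutation p under 0.05 by r and 5 by rho. By Pearson's r, the smallest p were those of the cancer interferon score with stroma inflammatory fibroblasts (r = 0.54, permutation p = 0.013, adjusted p = 0.36; rho = 0.35, permutation p = 0.14) and of classical minus basal-like with activated stroma (r = −0.52, permutation p = 0.025, adjusted p = 0.36; rho = −0.61, permutation p = 0.0068). Classical minus basal-like with myofibroblastic fibroblasts followed (r = −0.48, permutation p = 0.044, adjusted p = 0.36; rho = −0.49, permutation p = 0.035). Without the 2 farthest patients these r were 0.17, −0.46 and −0.44. Given the library totals, the classical minus basal-like relations had r = −0.31 and −0.26 (permutation p = 0.2 and 0.29). By rho, cancer proliferation with stroma myofibroblastic fibroblasts (rho = 0.55, permutation p = 0.015, adjusted p = 0.31; r = 0.37, permutation p = 0.12), interferon with T cells (rho = 0.53, permutation p = 0.021; r = 0.46, permutation p = 0.046) and proliferation with activated stroma (rho = 0.51, permutation p = 0.026; r = 0.37, permutation p = 0.12) came before the last of these. Without the 2 farthest patients their r were 0.31, 0.33 and 0.35. Given the carry-over between captures, proliferation had r = 0.17 with myofibroblastic fibroblasts and 0.10 with activated stroma (permutation p = 0.5 and 0.68). Classical minus basal-like then had r = −0.46 with activated stroma and −0.46 with myofibroblastic fibroblasts (permutation p = 0.049 each). Interferon with inflammatory fibroblasts had r = 0.56 given the carry-over and 0.52 given the library totals (permutation p = 0.01 and 0.021). Without the pair of the library that did not match its labels, interferon with inflammatory fibroblasts had r = 0.29 (permutation p = 0.25) and proliferation with myofibroblastic fibroblasts r = 0.65 (permutation p = 0.0037, adjusted p = 0.18). Proliferation with activated stroma had r = 0.56 without that pair (permutation p = 0.013, adjusted p = 0.21). Proliferation with stroma macrophages had r = 0.60 without that pair (permutation p = 0.0091, adjusted p = 0.21). With all 19 pairs, this macrophage relation had r = 0.45 (permutation p = 0.049), and r = 0.29 given the carry-over (permutation p = 0.22). Without that pair, none of the 48 passed.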

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

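Tests with abundant genes alone, with limma-voom without weights and without the pair of the library that did not match its labels were chosen after the data were seen. The others were planned. The counts to compare are 638 genes higher in stroma and 865 in cancer, of which 569 and 775 by at least 2-fold. Without the replicate block for the pairing, they were 524 and 222 (199 by at least 2-fold in cancer). With the block, DESeq2 gave 1380 and 2268 (1134 and 1953), limma-voom with quality weights 1811 and 1870 (1364 and 1204), with the patient as a random effect 982 and 1650 (1479 in cancer by at least 2-fold), and limma-voom without weights 1142 in stroma (963). Leaving out the 4 pairs of low total gave 338 and 482 (313 and 432), which are fewer samples. The acinar covariate gave 258 and 259 (245 and 244). Testing against 1.5-fold, a stricter hypothesis, gave 340 and 468, all above 2-fold. For the other tools and the block, the cause was not tested. In simulated counts drawn from edgeR's fitted means and dispersions, 80 of 219 DESeq2 calls were false (36.5%), and 4 of 121 with quality weights (3.31%). These shares need not hold for the real calls.

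Other scaling factors, filters, thinning and removal of mitochondrial and immunoglobulin genes kept these counts within 1.5 times. The filter planned as stricter kept 13400 genes, more than the 12373 of the main test, so a filter for abundant genes was added, which called 1187 of 6937 genes. Upper-quartile scaling moved the median log2 fold change of all genes from −0.27 to −0.37. With 1 pair left out, 435 to 756 genes were higher in stroma and 647 to 929 in cancer, 15 of the 111 named genes that passed lost their call in at least 1 case (IGKC in 15 of 19 cases, IL7R in 14, CCL2, LMOD1, NOTCH3 and OGN in 13, CD55 in 12, VTCN1 in 9, ABCA8 in 8, the others in 6 or fewer), and 18 to 19 lists were higher in stroma and 7 to 8 in cancer. Of 5564 values of named genes under alternatives, 5076 kept their side of the threshold, 294 lost the threshold and 193 passed it. Direction was compared only where a gene passed in the main test or in the alternative. HBB alone turned there: it did not pass in the main test (−0.03) and had 5.2 without the replicate block.

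With an estimated correlation, 7 lists were higher in stroma and 2 in cancer. Without a filter, 12 were higher in cancer, adding drivers, interferon, islet, mitochondrial and ribosomal genes, the last of which also passed in 2 other settings, and the basement membrane list no longer passed. Without the block, the proliferation and glycolysis lists no longer passed, and no other list changed its call. Activated and normal stroma scores fell from r = 0.65 to −0.001079 without the 2 farthest patients and to 0.20 without the pair of the unmatched library. For myofibroblastic and inflammatory fibroblasts, r fell from 0.69 to 0.455 and 0.241. The other relations kept their side of the threshold under every setting run. At the depth and spread of these libraries, 4% of simulated 2-fold changes were found, and depth was not varied in the simulation.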

Other observations

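The genes of the first 2 paragraphs were chosen after their values were seen, from ligands, receptors, integrins and others looked up. Of these, 53 passed the count filter and were tested, of which 14 were higher in stroma and 9 in cancer. IGF1, NRG1 and IL6 were among those looked up but not tested. FGF7, a growth factor for epithelium, was at 6.75 ± 10.95 CPM in cancer and 44.1 ± 53.2 CPM in stroma (SD, n = 19; log2 fold change 4.11), and MET, the receptor of HGF, at 236 ± 170 CPM in cancer and 100.1 ± 134 CPM in stroma (−1.70). The adjusted p of edgeR's quasi-likelihood test were 0.0041 and 0.00586. FGFR2 had a log2 fold change of −1.20 and did not pass (adjusted p = 0.517, edgeR quasi-likelihood). GREM1, an antagonist of bone morphogenetic proteins (2.65), WNT2 (3.15), WNT5A (2.21), the AXL ligand GAS6 (1.38), the semaphorin SEMA3C (1.55) and its coreceptor NRP1 (1.25) were higher in stroma, while ERBB3 (−2.03) and the ephrin EFNA1 (−1.74) were higher in cancer. AXL itself (1.12, adjusted p = 0.215) and PTCH1, a receptor and target of hedgehog signalling (0.67, adjusted p = 0.558), did not pass the same edgeR quasi-likelihood test.

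Among integrin genes looked up, ITGB4, part of the hemidesmosome, was higher in cancer in 19 of 19 pairs (235 ± 122 against 52.9 ± 42.2 CPM, SD, n = 19; edgeR quasi-likelihood adjusted p = 6.97e-05), with ITGB6 (−1.88) and ITGA2 (−0.93). ITGA11, a collagen receptor of fibroblasts (2.84), and ITGA5 (1.77) were higher in stroma, and ITGA6 (−0.90, edgeR quasi-likelihood adjusted p = 0.0975) did not pass. DUOXA2, which matures an oxidase of mucosal surfaces, had a log2 fold change of −5.26 ± 1.03 (SE). DUOX2, whose annotated end overlaps it, had −1.66 and did not pass. GATA6, a factor tied to the classical subtype, did not pass (0.48 ± 0.51, SE; edgeR quasi-likelihood adjusted p = 0.594).

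The tests of a background of equal share, of other splits and of acinar genes without PRSS1 were chosen after results were seen. The count of 1503 called genes was compared with other splits, in which compartments were exchanged at random within pairs so that every split parts the 19 pairs. Of 40 splits, 1, the real one, gave as many genes, and the highest of the others gave 0. In the other splits, the compartment difference of the exchanged pairs adds to the spread, which lowers their calls. With 40 splits, the comparison makes chance unlikely for this count but cannot exclude it. In 20 such splits, the others gave a median of 2 genes with DESeq2 and 0 with quality weights. The highest of them gave 105 and 188, against 3648 and 3681 for the real one.

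Tumour genes were present in the stroma captures, at 0.302 times the cancer level for epithelial genes. A background that takes an equal share of every stroma library, as the only source, is argued against. The epithelial level in CPM differed 21.4-fold between the lowest and the highest stroma library. Levels in CPM cannot test a background of equal absolute amount, whose share would change with the amount of RNA captured. RNA of the adjacent cancer cells is a candidate source: across 19 patients the classical minus basal-like score of the stroma library followed that of the patient's own cancer library, with r = 0.837 (permutation p = 3e-05; rho = 0.844, permutation p = 5e-05; r = 0.724 without the 2 farthest patients). Whether whole cancer cells or free RNA were captured stays open, as does a handling step shared by the 2 libraries of a patient, which the labels do not give. No biological explanation was tested.

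Acinar genes were higher in the cancer captures, by a mean log2 difference of −2.41 for stroma against cancer. Deeper cancer libraries are argued against, as the difference was −2.39 after thinning to equal totals (permutation p = 0.00044, lower in stroma in 14 of 19 pairs). Expression of PRSS3, REG1A and REG1B alone stays open: the other acinar genes differed by −2.18 (sign-flip permutation p = 0.00777, lower in stroma in 15 of 19 pairs), but by −0.84 ± 2.79 (SD, n = 19; permutation p = 0.208) without PRSS1, a close paralog of PRSS3 that can share its reads, so the planned bound may not remove the signal of PRSS3. PRSS1 had reads in 13 cancer and 7 stroma libraries, with medians of 7.94 and 0 CPM, and its cancer mean of 194 ± 749 CPM (SD, n = 19) rests on few libraries. Acinar cells caught beside the cancer glands and acinar genes expressed by cancer cells both stay open and may each contribute.

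With the acinar score as a covariate, the called genes fell from 1503 to 517. Acinar RNA as the maker of the 999 lost calls is argued against: their fold changes stayed at a median of 0.96 times the value without the covariate (quartiles 0.85 and 1.06), with a median size of 2.17 on the log2 scale before and 2.04 after. A covariate that differs between compartments and takes up part of the contrast is a candidate explanation, since 6 of 20 random covariates with the same within-pair difference left no more calls (range 178 to 1217, median 598.5). Errors of the lost calls grew, from a median SE of 0.626 to 0.777 (median ratio 1.25, quartiles 1.23 and 1.27). The errors of the calls that were kept were not compared. No biological explanation was tested.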
